A study of Homo sapiens with 12 samples.

How the data were processed

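Nascent RNA was measured by sequencing in 12 libraries of 2 human leukaemia cell lines that carry the t(4;11) translocation, SEM and RS4;11. Per the labels' protocols, cells were electroporated with an siRNA and treated with 4-thiouridine (4sU), a uridine analogue that is built into RNA made during the labelling. The labelled RNA was coupled to biotin, collected on streptavidin beads and made into strand-specific libraries. Length of the 4sU pulse and time between electroporation and harvest are not given in the sources used here. SEM libraries carried a RUNX1 siRNA or a non-targeting control siRNA, and RS4;11 libraries carried an siRNA against the KMT2A-AFF1 (MLL-AF4) fusion transcript or its control siRNA, with 3 libraries in each of the 4 groups. Groups were taken from the sample titles and the siRNA named for each sample. A free-text description of the 3 RS4;11 libraries titled with the KMT2A-AFF1 siRNA calls them non-targeting, and the titles and the siRNA field were followed. The series design text gives 3 samples for each biological group and the labels number them 1 to 3. Nothing beyond these labels states that the replicates came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical.

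The deposited values are raw counts per gene, 1 table for each cell line with the same 26364 genes, and 0 entries named no gene. Per the submitters' processing notes, reads were handled with STAR, Picard, featureCounts of the Subread package and edgeR, and the genome build was hg19. Versions of STAR, Picard and edgeR are not given in the sources used here. Per the file headers, the RS4;11 counts were made with featureCounts 2.0.0 over the exons of the UCSC hg19 gene annotation, summed by gene, as read pairs and with the setting for reverse-stranded libraries. By that tool's defaults, reads that map to several places or overlap several genes are then not counted, so near-identical genes such as histones, ribosomal protein genes with pseudogenes and gene families can lose counts. The deposited SEM counts have the same genes, exon coordinates and layout but no command line, so whether strand was used is not given in the sources used here. Values of SEM genes with an overlapping or antisense partner are uncertain for that reason. Exon counts of nascent RNA leave out the intronic reads of unspliced transcripts, and gene counts cannot separate the KMT2A-AFF1 fusion transcript from the normal KMT2A and AFF1 transcripts. Library totals and gene coordinates were taken from the same deposited tables, and coordinates are hg19.

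Each cell line was tested separately with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings (a minimum count of 10 in enough libraries and a minimum total of 15), library sizes were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood F test was run with robust estimation of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no fold threshold. Levels are given as CPM on TMM-scaled library sizes, as mean and SD of 3 libraries, and every log2 fold change is siRNA against control. The difference between the knockdowns was tested as an interaction in 1 edgeR fit of all 12 libraries with 4 group means, as the change in RS4;11 minus the change in SEM. Target and cell line differ together in that test. Overlap of the called genes was set against the number that independent lists of the same sizes give, with Fisher's exact test, 2-sided, for each pair of directions. The cell lines share no control libraries.

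A set of 26 gene lists was fixed in advance, covering lineages, cell cycle, stress, signalling and chromatin complexes. Lists were tested with camera of limma 3.58.1, called through edgeR on the counts, which turns them into z-scores under the fitted count model. Camera's direction can therefore differ from the sign of a list's median or mean log2 fold change. The preset correlation between genes was 0.01, and tests were 2-sided with Benjamini-Hochberg adjustment over the 26 lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation camera also rests on the residual degrees of freedom of the fit, which are few here. A call lost under that setting can therefore come from the smaller degrees of freedom as well as from correlated genes. Members of a list were counted as higher or lower at an adjusted p under 0.05 over all genes tested and, separately, adjusted over the list alone. Symbols in the lists are those of the deposited tables. In this annotation CD24 has its entry on chromosome Y, so its level is not given, and the B-cell list was also tested without it.

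Named genes followed a fixed rule. It takes RUNX1, KMT2A, AFF1, MYC, BCL2 and CASP9, and the 8 largest increases and 8 largest decreases of each comparison among called genes whose 3 siRNA libraries all lay on one side of the 3 controls and whose average log2 CPM was at least 3. It adds up to 4 called members with the smallest p of each list, and the 5 genes in the same direction and the 5 in opposite directions with the smallest p among those called in both comparisons. Non-coding, mitochondrial, Y-linked and open-reading-frame symbols and histone genes were left out of the largest changes and of the shared genes. PAX5, EBF1, ATF4, DDIT3, HOXA7, HOXA9, HOXA10 and MEIS1 lie outside the rule and were chosen after their values were seen. Groups, tests, gene lists, the rule for named genes and the alternatives were set before the data were examined, except where an alternative or test is said to have been chosen later.

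The alternatives were scaling by relative log expression, by upper quartile and by library totals alone, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, an adjusted p under 0.01, a fold of at least 1.5, the replicate number as a block, both cell lines in 1 fit, and leaving out each library in turn. Added after seeing the data were SEM counts thinned to 4061914 counts per library, the B-cell list without CD24, and a fit without RUNX1 siRNA library 1 and control library 3. The stricter p and the fold threshold were applied to counts of genes only and are not among the alternatives counted for single genes. DESeq2 adjusted p-values given as NA were left as NA. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

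The procedure was tested on simulated counts drawn from the means and library sizes of the real samples, with 200 genes changed by known folds. In the simulation of the SEM comparison, 36% of genes changed 1.25-fold, 76% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold were called among 13613 genes tested, and 6 of 13416 unchanged genes were called. In that of the RS4;11 comparison the shares were 26%, 80%, 88% and 94% among 11953 genes tested, with 6 of 11757 unchanged genes called. For the difference between the knockdowns they were 10%, 36%, 78% and 84% among 13628 genes tested, with 7 of 13430 unchanged genes called. A list whose members were changed 1.5-fold was called in both simulated comparisons, while 0 of 24 unchanged lists were called by camera in either. Simulated genes were drawn independently of each other, whereas the correlation estimated for the real histone list in SEM was 0.91. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Of 100 genes changed in the same direction in both simulated comparisons 95 were found, of 100 changed in opposite directions 90 were found, and 0 others were called in both, among 11710 genes.

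Replicates were compared before averaging. In every pair of libraries of a group, counts differed by more than sampling noise, with a chi-square per degree of freedom between 1.71 and 7.38, so none were repeat counts of 1 library. Repeat preparations of 1 sample would differ in this way too, so this does not show that they are separate samples. Library totals ran from 10040657 to 13901317 counts in SEM and from 3791687 to 4423360 in RS4;11, and the 10 highest genes held between 2.02% and 2.40% of a library. Reads carry no molecular identifiers, so counts may include copies of 1 molecule.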

Results

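Newly made RNA was sequenced in SEM and RS4;11 cells, B-lineage acute lymphoblastic leukaemia lines whose t(4;11) translocation makes a fusion of KMT2A (MLL), a histone methyltransferase, and AFF1 (AF4), a part of the super elongation complex. SEM cells had received an siRNA against RUNX1, a transcription factor needed for definitive blood formation, or a non-targeting siRNA. RS4;11 cells had received an siRNA against the KMT2A-AFF1 fusion transcript or its control siRNA. Each of the 4 groups had 3 libraries. Totals of the 6 SEM libraries ran from 10040657 to 13901317 counts and those of the 6 RS4;11 libraries from 3791687 to 4423360 counts. The series title names a KMT2A-AFF1 regulatory network and its core transcription factors, and the comparisons ask which genes changed their synthesis when RUNX1 or the fusion was targeted.

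In the SEM libraries labelled RUNX1 siRNA, 13 of 20 measured genes of the B-cell lineage rose, while 16 of 23 genes of G1 and S phase, 13 of 20 genes of G2 and M phase and 12 of 14 genes of cholesterol synthesis fell (edgeR). The named gene with the largest increase was ZNF521, a zinc finger cofactor of blood progenitors, which went from 3.06 ± 0.430 to 85.6 ± 3.29 CPM (SD, n = 3). The lymphoid transcription factor BACH2 went from 52.6 ± 6.87 to 226 ± 6.91 CPM (SD, n = 3). CEBPA, a myeloid transcription factor, had a log2 fold change of -0.96 ± 0.08 (standard error, n = 3), and RUNX1 itself was not lower.

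RUNX1 (chromosome 21, 36160098 to 36421595, minus strand, hg19) had 1516, 1522 and 1618 CPM in the 3 control libraries and 1646, 1697 and 1684 CPM in the 3 libraries labelled RUNX1 siRNA. The log2 fold change was 0.11 with a standard error of 0.05, and the edgeR adjusted p was 0.0796. Over 17 alternatives the adjusted p of RUNX1 (edgeR, DESeq2 or limma-voom) ran from 0.0281 to 0.236. It passed the threshold, with RUNX1 higher, under upper quartile scaling (0.0485), library totals alone (0.0281), limma-voom (0.0466) and without control library 3 (0.0495, edgeR). The counts come from newly made RNA, so they compare RUNX1 synthesis between the groups as labelled, and a change in it did not pass in the main fit. Mature RUNX1 RNA and protein were not analysed here, and these values did not settle the RUNX1 labels. Of the family members, RUNX3 rose by 0.90 ± 0.13 (standard error) on the log2 scale and RUNX2 by 0.29 ± 0.05, with edgeR adjusted p of 3.32e-05 and 0.000380. In the list of the RUNX family and CBFB, 2 of 4 measured members were higher and 0 lower, 3 and 0 when adjusted over the list alone, and the camera adjusted p was 0.298.

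KMT2A (chromosome 11, 118307205 to 118397539, plus strand) and AFF1 (chromosome 4, 87856154 to 88062206, plus strand) did not pass in SEM. KMT2A was at 537 ± 22.9 CPM in controls and 578 ± 5.91 CPM with the siRNA, and AFF1 at 369 ± 22.7 and 349 ± 6.02 CPM (SD, n = 3). Their edgeR adjusted p were 0.115 and 0.275, and that of AFF1 was 0.0236 with a log2 fold change of -0.14 without control library 1. MYC, a growth-promoting transcription factor (chromosome 8, 128748315 to 128753680, plus strand), had a log2 fold change of -0.10 and an edgeR adjusted p of 0.355. Its sign turned without control library 1, to 0.015. BCL2, which blocks apoptosis (chromosome 18, 60790579 to 60986613, minus strand), fell by 0.33 on the log2 scale, from 521 ± 13.6 to 415 ± 14.4 CPM (SD, n = 3), with an edgeR adjusted p of 6.77e-05. CASP9, an initiator caspase (chromosome 1, 15817896 to 15851285, minus strand), had a log2 fold change of 0.32 and an edgeR adjusted p of 0.0435, which held in 6 of 17 alternatives, with a range from 0.0260 to 0.211 by edgeR, DESeq2 or limma-voom. That call was lost without control library 1 (0.153), control library 2 (0.0592), or siRNA library 1 (0.113), 2 (0.0850) or 3 (0.122), with no filter (0.0580), with both cell lines in 1 fit (0.0739) and with DESeq2 (0.211), among others.

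**Figure D1:**
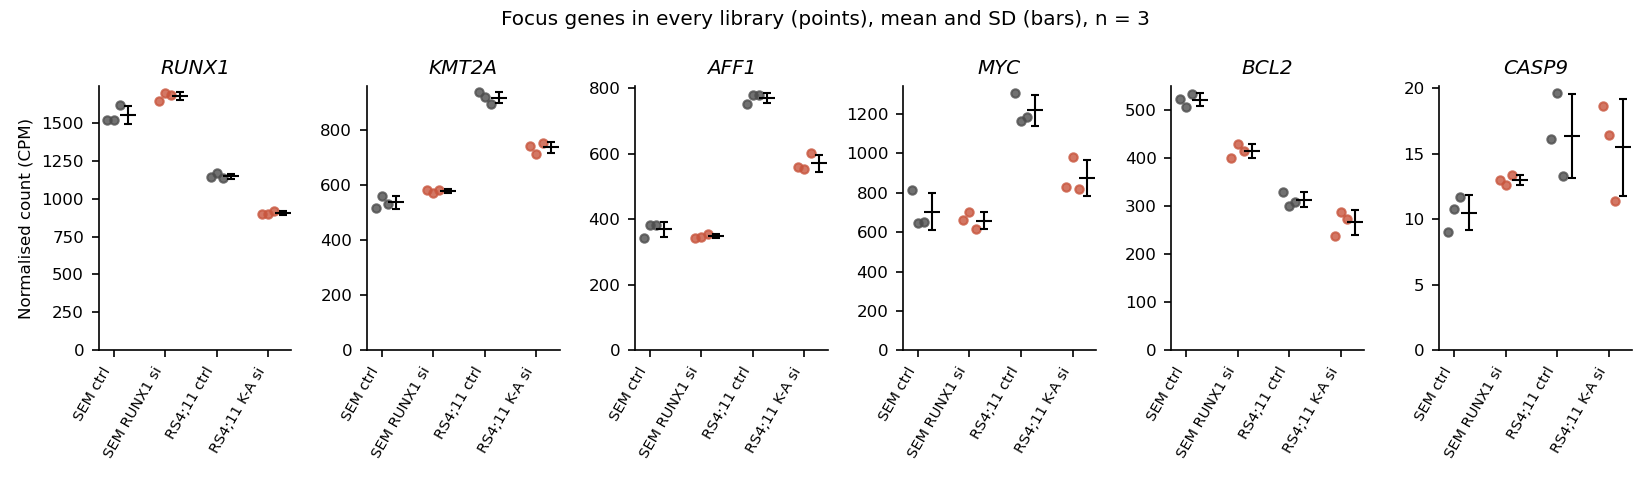
Normalised counts (CPM, vertical axes from 0) of 6 genes in each library (points; grey, control siRNA; red, targeting siRNA), with mean and SD of 3 libraries as bars beside them; K-A si is the KMT2A-AFF1 siRNA. RUNX1 lay at 1552 CPM in SEM controls and 1676 CPM in the libraries labelled RUNX1 siRNA, and at 1147 and 904 CPM in RS4;11.

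Of 13733 genes tested in SEM, edgeR called 2443 higher and 2279 lower, or 34.4% of those tested. Most changes were small. Only 476 of the higher and 121 of the lower genes changed at least 2-fold, and the median size of a called change was 0.40 on the log2 scale. In 6205 genes (45.2%) the 3 siRNA libraries did not overlap the 3 controls, where chance gives 10%. RUNX1 siRNA library 1 stood apart from the other SEM libraries by low counts in otherwise silent genes, with 20728 genes detected against 16827 to 17285. Without that library 1847 genes were higher and 1540 lower. The counts also fell without siRNA library 2, to 1981 and 1795, and without siRNA library 3, to 2045 and 1715, so a fall was not particular to library 1. Without library 1 and control library 3 together, an alternative chosen after seeing the data, 1627 were higher and 1312 lower.

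**Figure D2:**
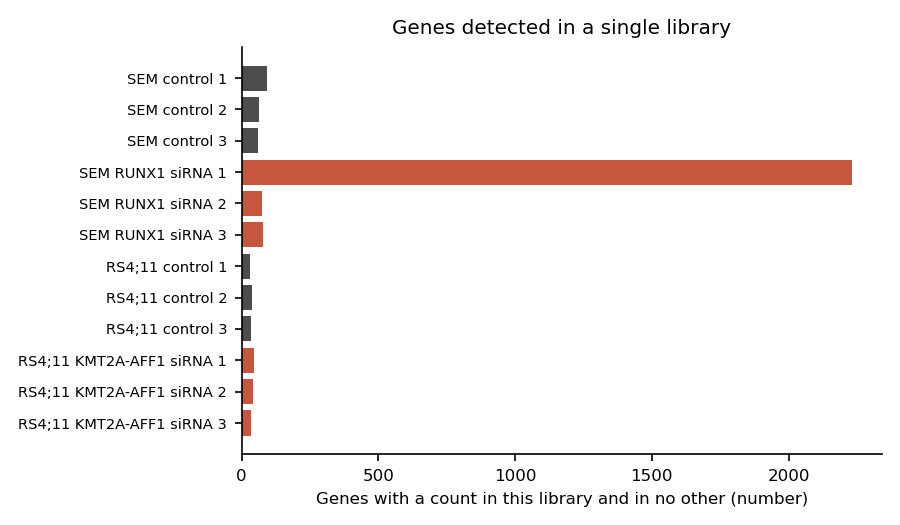
Number of genes (horizontal axis, from 0) with a count in the named library and in none of the other 11, as a bar for each of the 12 libraries (grey, control siRNA; red, targeting siRNA). SEM RUNX1 siRNA library 1 had 2230 such genes and the other libraries 32 to 93.

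Among the other named increases were NCKAP5 at a log2 fold change of 4.66, ATXN1 at 3.16 and ROR1, a receptor kinase of fetal and leukaemic B cells, at 3.06. DOCK9, an activator of the GTPase CDC42, was at 3.66, the potassium channel gene KCNJ2 at 3.00, NAV2 at 2.89 and EFR3B at 2.88. Among the named decreases, SORBS2, an adaptor of the actin cytoskeleton, went from 15.1 ± 2.80 to 1.01 ± 0.0424 CPM (SD, n = 3). The protease inhibitor A2M had a log2 fold change of -2.38, the ephrin receptor EPHB3 -2.19 and FUT7, a fucosyltransferase that makes selectin ligands, -2.12. CHAC1, which degrades glutathione, was at -2.10, PLCH1 at -2.06, the proteoglycan gene VCAN at -1.88 and PRKCQ, a protein kinase C of lymphocytes, at -1.51. The edgeR adjusted p of these 15 genes ran up to 0.000564, that of CHAC1.

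In the B-cell lineage list, 13 of 20 measured members were higher and 0 lower in SEM, and 14 and 0 when adjusted over the list alone. The recombinase gene RAG2 rose from 19.7 ± 1.31 to 52.9 ± 2.65 CPM, the adaptor of B-cell receptor signalling BLNK from 3.40 ± 1.09 to 17.0 ± 1.52 CPM, and the surface receptor CD22 from 75.4 ± 2.19 to 157 ± 5.42 CPM (SD, n = 3). FOXO1, an activator of the recombinase genes, rose by 1.60 on the log2 scale with an edgeR adjusted p of 4.04e-07. PAX5 and EBF1, which set B-cell identity, did not pass, at log2 fold changes of 0.07 and 0.10 (edgeR adjusted p of 0.302 and 0.127). Camera gave the list an adjusted p of 2.64e-14, and the adjusted p was 0.0243 with an estimated correlation. Without CD24, chosen as an alternative after seeing the data, 12 of 19 members were higher, and the camera adjusted p was 1.62e-09 and 0.0538 with an estimated correlation. With that correlation and any 1 library left out, the adjusted p of the whole list was 0.0770 to 0.128.

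Haematopoietic transcription factors moved both ways in SEM, with 8 of 18 measured members higher and 4 lower, the same numbers when adjusted over the list alone, and a camera adjusted p of 0.179. IKZF1, a lymphoid regulator, rose from 245 ± 5.39 to 468 ± 19.5 CPM (SD, n = 3). NFE2, a factor of megakaryocytes and red cells, fell by 2.67 on the log2 scale, with an edgeR adjusted p of 1.73e-07. The KMT2A fusion target list had 7 of 24 members higher and 3 lower, 7 and 5 when adjusted over the list alone, with a camera adjusted p of 0.580. EYA1 rose by 1.24 and HOXA3 by 0.79 on the log2 scale, while ZEB2, a repressor of lymphoid and myeloid genes, fell by 0.46, with edgeR adjusted p of 3.14e-07, 5.81e-07 and 4.23e-07. In the myeloid list 2 of 8 measured members were higher and 4 lower, 2 and 5 when adjusted over the list alone, at a camera adjusted p of 0.298. CSF1R, the receptor of macrophage colony-stimulating factor, fell by 0.92, while ANPEP, an aminopeptidase of myeloid cells, rose by 0.95 on the log2 scale.

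Of 23 measured G1 and S phase genes 16 were lower and 1 higher, 17 and 2 when adjusted over the list alone, with a camera adjusted p of 0.000245 but an adjusted p of 0.545 with an estimated correlation. CDC25A, a phosphatase that opens S phase, fell by 0.58 and MCM4, a subunit of the replicative helicase, by 0.44 on the log2 scale. The 1 higher member was the cyclin gene CCND1, from 2.54 ± 0.0729 to 11.1 ± 1.10 CPM (SD, n = 3). Of 20 G2 and M phase genes 13 were lower and 0 higher, 15 and 0 when adjusted over the list alone, with a camera adjusted p of 0.000241 and an adjusted p of 0.545 with an estimated correlation. CDK1, the mitotic kinase, fell from 237 ± 8.89 to 166 ± 5.53 CPM (SD, n = 3). Of 16 replication-dependent histone genes 15 were lower, 16 when adjusted over the list alone, among them HIST1H2AC at -0.42 and HIST1H4C at -0.38. Camera gave the histones an adjusted p of 0.000579, and the adjusted p was 0.545 with an estimated correlation and 0.103 with fry. Reads of near-identical histone genes are shared or lost in counting, so single histone genes are uncertain.

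Of 18 genes of the unfolded protein and integrated stress response 11 were lower and 1 higher, 12 and 1 when adjusted over the list alone, with a camera adjusted p of 3.05e-06 and an adjusted p of 0.545 with an estimated correlation. PHGDH and PSAT1, enzymes of serine synthesis, had log2 fold changes of -0.88 and -0.94, the lipoprotein receptor gene VLDLR of -1.14 and the stress transcription factor gene ATF3 of -0.83. ATF4 and DDIT3, the central factors of this response, did not pass, at log2 fold changes of -0.08 and -0.17. The 3 controls were spread on this list, with medians of -0.02, -0.12 and 0.18 on a log2 scale around their mean, against -0.46, -0.30 and -0.41 in the 3 siRNA libraries. Of 14 cholesterol synthesis genes 12 were lower and 0 higher, 12 also when adjusted over the list alone, with a camera adjusted p of 3.89e-05 and an adjusted p of 0.545 with an estimated correlation. INSIG1, a sterol sensor, fell from 649 ± 49.4 to 438 ± 19.5 CPM and HMGCS1, an early enzyme of the pathway, from 412 ± 39.8 to 280 ± 9.07 CPM (SD, n = 3). Of 24 MYC-responsive genes of ribosome biogenesis and metabolism 11 were lower and 0 higher, 11 also when adjusted over the list alone, with a camera adjusted p of 0.0290 and an adjusted p of 0.545 with an estimated correlation. NOP58, which guides methylation of ribosomal RNA, fell by 0.31 on the log2 scale. The call of this list was lost without control library 1 (camera adjusted p = 0.124) and without siRNA library 1 (0.0502). Camera passed 7 of the 26 lists in SEM, and other splits of the same 6 libraries passed up to 9. Each other split mixed siRNA and control libraries unevenly, so part of the siRNA change stays in it and these splits do not show what chance gives. Of the lists passed in SEM only the B-cell list also passed with an estimated correlation. That setting is weaker by itself, as the B-cell list had an estimated correlation of -0.015, below the preset 0.01. Its camera adjusted p still went from 2.64e-14 to 0.0243. A call lost under that setting therefore does not measure the part of gene correlation. In the other lists passed, the estimated correlation ran from 0.23 (G1 and S phase) to 0.91 (histones). A list call with the preset correlation is thus weak evidence here.

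**Figure D3:**
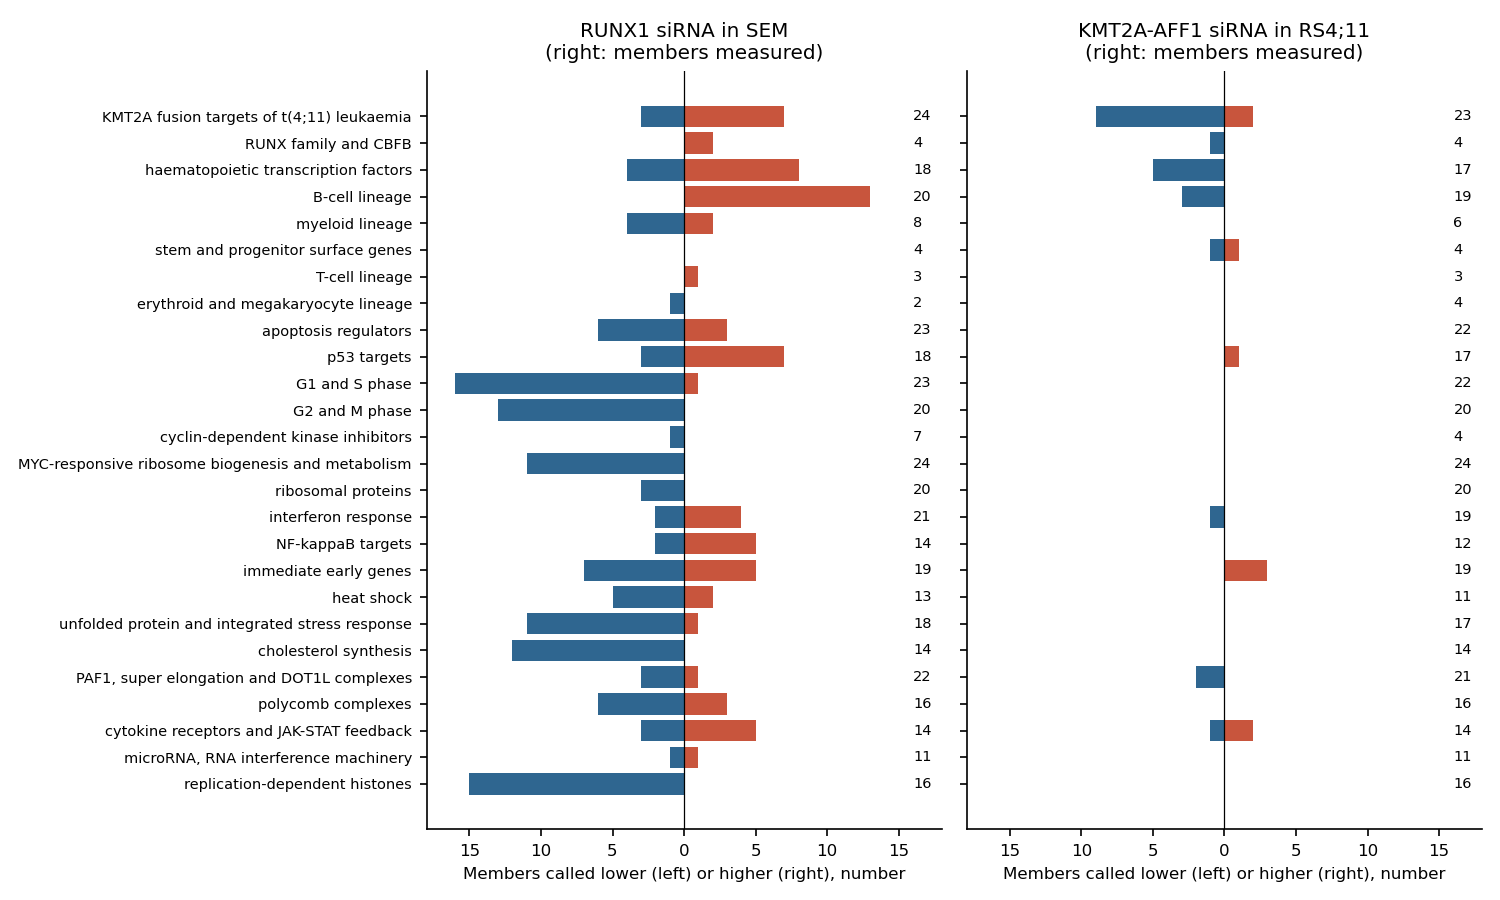
Members of each of the 26 gene lists called lower (blue, left) or higher (red, right) by edgeR at an adjusted p under 0.05 over all genes, as numbers of genes on the horizontal axis, in the SEM comparison (left panel) and the RS4;11 comparison (right panel), with the members measured printed at the right. In SEM 13 of 20 B-cell genes were higher and 16 of 23 G1 and S phase genes lower; in RS4;11 9 of 23 KMT2A fusion targets were lower.

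In RS4;11 cells that received the KMT2A-AFF1 siRNA, 9 of 23 measured targets of the fusion fell and 2 rose (edgeR), and counts of the fusion partners KMT2A and AFF1 fell as well. CPEB2, a translation regulator, fell from 274 ± 14.9 to 143 ± 4.73 CPM, and PROM1, which encodes the stem cell surface protein CD133, from 460 ± 23.9 to 291 ± 9.79 CPM (SD, n = 3). MYC fell from 1219 ± 77.6 to 877 ± 91.1 CPM and RUNX1 from 1147 ± 18.3 to 904 ± 13.9 CPM (SD, n = 3). Some genes of the early response to growth signals rose, such as the transcription factor gene JUN from 26.2 ± 5.28 to 44.6 ± 10.2 CPM (SD, n = 3).

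KMT2A had 937, 920 and 895 CPM in the 3 RS4;11 control libraries and 744, 714 and 753 CPM in the 3 KMT2A-AFF1 siRNA libraries. Its log2 fold change was -0.32 with a standard error of 0.07, and the edgeR adjusted p was 0.0156. AFF1 had 753, 778 and 778 CPM in controls and 558, 554 and 601 CPM with the siRNA. It fell by 0.43 on the log2 scale with a standard error of 0.07 and an edgeR adjusted p of 0.000717. Counts per gene hold the fusion and the normal transcripts together. RUNX1 had 1140, 1168 and 1134 CPM in controls and 896, 896 and 920 CPM with the siRNA, a log2 fold change of -0.34 with an edgeR adjusted p of 0.00630. The call of KMT2A was lost without control library 1 (0.0507), control library 3 (0.0515) or siRNA library 2 (0.144), with edgeR, DESeq2 or limma-voom adjusted p from 0.000209 to 0.144 over 15 alternatives. That of RUNX1 was lost without siRNA library 2 (0.0706), with a range by the same 3 tools from 9.41e-06 to 0.0706, and those of AFF1 and MYC held in all 15. The fold of at least 1.5 is not among these 15, and AFF1 and MYC changed 1.35-fold and 1.39-fold. BCL2 was at 313 ± 15.3 and 266 ± 25.9 CPM and CASP9 at 16.3 ± 3.19 and 15.5 ± 3.68 CPM (SD, n = 3), with edgeR adjusted p of 0.170 and 0.938.

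Of 12062 genes tested in RS4;11, edgeR called 100 higher and 106 lower, or 1.71%, of which 8 and 16 changed at least 2-fold. At an unadjusted p under 0.05 there were 1383 genes. In 1941 genes (16.1%) the groups did not overlap, where chance gives 10%. The counts moved with the libraries used. Without control library 2, 53 genes were higher and 94 lower, without control library 3, 54 and 62, and without siRNA library 2, 50 and 53. They were 102 and 87 without control library 1, 71 and 99 without siRNA library 1, and 143 and 109 without siRNA library 3. A fit with fewer libraries can also call fewer genes for that reason alone.

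The named gene with the largest increase was GNAQ, the alpha subunit of a heterotrimeric G protein, from 74.7 ± 7.32 to 178 ± 12.1 CPM (SD, n = 3), with an edgeR adjusted p of 3.94e-10. FRMPD1 followed at a log2 fold change of 1.12, FCRLA, a gene of B cells, at 1.06, UAP1L1 at 1.06, and SMAD7, an inhibitor of TGF-beta signalling, at 0.93. GATA3, a T-lineage transcription factor, was at 0.92, HSPB7 at 0.90 and RGS2 at 0.89. The named gene with the largest fall was EGLN1, an oxygen-sensing prolyl hydroxylase, from 136 ± 2.04 to 58.5 ± 3.31 CPM (SD, n = 3), a log2 fold change of -1.22 with an edgeR adjusted p of 3.94e-10. MBOAT1, EFEMP1 and RAG1 each had a log2 fold change of -1.07, PRSS12 of -1.02, CPEB2 of -0.94, HMGA2, a chromatin protein of early development, of -0.88 and HR of -0.86. The call of SMAD7 was lost without control library 2 (0.164) or siRNA library 2 (0.0958), that of UAP1L1 without control library 3 (0.0788) or siRNA library 1 (0.0540), and that of EFEMP1 without siRNA library 2 (0.0717), all edgeR adjusted p. HR kept its call in 9 of 14 alternatives, and its edgeR adjusted p was 0.222, 0.0576 and 0.0515 without control libraries 1, 2 and 3 and 0.162 and 0.136 without siRNA libraries 2 and 3. Over all alternatives, the 15 named RS4;11 genes whose call was lost in some had edgeR, DESeq2 or limma adjusted p of up to 0.273.

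The list of KMT2A fusion targets had 9 of 23 measured members lower and 2 higher, 14 and 2 when adjusted over the list alone. Lower members besides CPEB2, PROM1, MYC, RUNX1 and HMGA2 were ZEB2, which fell by 0.56 on the log2 scale, LMO2, a stem cell transcription cofactor, and the homeobox genes HOXA10 and HOXA7. ARID1B, a subunit of a chromatin remodelling complex, rose by 0.65 with an edgeR adjusted p of 3.38e-06, and the receptor kinase gene FLT3 had a log2 fold change of 0.32 with an edgeR adjusted p of 0.0421. HOXA9 and MEIS1 did not pass, at log2 fold changes of -0.14 and -0.20. Camera gave the list an adjusted p of 5.36e-18, and the adjusted p was 0.0348 with an estimated correlation. With that correlation, it was 0.0735 under upper quartile scaling, 0.0664 with library totals alone, 0.0987 with no filter and 0.0799 to 0.215 with any 1 library left out. The list came from published knowledge of such cells, in part of the same lines, so it is not independent of them. The call of LMO2 was lost without control library 1 (0.111) or 3 (0.153) or siRNA library 2 (0.0958) or 3 (0.0711) and with DESeq2 (DESeq2 adjusted p = 0.0831), and that of FLT3 without control library 1 (0.118) or 3 (0.273) or siRNA library 1 (0.159), 2 (0.124) or 3 (0.0555), the others edgeR adjusted p.

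Haematopoietic transcription factors included 5 of 17 measured members that were lower and 0 higher, 5 and 2 when adjusted over the list alone. ERG, a factor of blood stem cells, fell from 306 ± 11.0 to 224 ± 16.4 CPM (SD, n = 3) with an edgeR adjusted p of 0.000961. Camera gave this list an adjusted p of 0.000403, with an adjusted p of 0.367 with an estimated correlation and 0.0860 with fry. Of 19 B-cell genes 3 were lower and 0 higher, 4 and 2 when adjusted over the list alone. RAG1 fell from 267 ± 33.3 to 128 ± 22.1 CPM and FOXO1 from 221 ± 5.59 to 142 ± 8.50 CPM (SD, n = 3), and RAG2 had a log2 fold change of -0.48 with an edgeR adjusted p of 0.0157. The call of RAG2 was lost without control library 1 (0.0596) or 3 (0.111) or siRNA library 1 (0.119), edgeR adjusted p. The list median was 0.06 and its mean -0.07, camera's direction was down, and its adjusted p was 0.218, and 0.0170 without control library 2.

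Immediate early genes, which answer growth and stress signals within minutes, had 3 of 19 members higher and 0 lower, 11 and 0 when adjusted over the list alone. Those past the threshold over all genes were JUN, KLF2 and EGR1, with log2 fold changes of 0.77, 0.69 and 0.68 and edgeR adjusted p of 0.00386, 0.00545 and 0.010. Camera gave the list an adjusted p of 1.14e-11, with an adjusted p of 0.551 with an estimated correlation and 0.374 with fry. Without control library 2 none of the 3 was called, at edgeR adjusted p of 0.0723, 0.0573 and 0.0884, EGR1 was also lost without control library 1 (0.0843), and KLF2 with both cell lines in 1 fit (0.0511). Of 22 G1 and S phase genes and 20 G2 and M phase genes edgeR called 0, and 0 and 1 when adjusted over the list alone. G2 and M phase genes had a median log2 fold change of -0.11, a camera adjusted p of 0.00668 (0.166 without siRNA library 1) and an adjusted p of 0.671 with an estimated correlation. The MYC-responsive list, ribosomal proteins and cholesterol synthesis genes were each past camera's threshold in the upward direction at an adjusted p of 0.0302, with 0 members called by edgeR, medians of 0.07, 0.08 and 0.12, and adjusted p of 0.671, 0.763 and 0.671 with an estimated correlation. These calls were lost without control library 1 (0.0555 and 0.0504), control library 2 (0.220 and 0.726), siRNA library 2 (0.0939 and 0.187) or siRNA library 3 (0.125 and 0.334) for the MYC-responsive and ribosomal lists, and without control library 3 (0.326), siRNA library 1 (0.334) or siRNA library 2 (0.0882) for cholesterol synthesis, all camera adjusted p. Camera passed 7 of the 26 lists in RS4;11 and up to 8 in other splits of the same 6 libraries. Those splits also mixed siRNA and control libraries, so part of the siRNA change stays in them.

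Among genes changed in both cell lines, the glycosyltransferase gene ST6GAL1 and the chromatin remodeller gene ARID1B rose in each, and ZEB2 fell in each. ST6GAL1 rose by 0.72 on the log2 scale in SEM and by 0.64 in RS4;11, ARID1B by 0.40 and 0.65, and ZEB2 had log2 fold changes of -0.46 and -0.56. NCKAP5 rose by 4.66 and 0.88, and the change of GNAQ in RS4;11 exceeded that in SEM by 0.74 (edgeR adjusted p = 3.43e-06 for the interaction). Other genes moved apart. FOXO1 rose by 1.60 in SEM and fell by 0.63 in RS4;11, and PVRL1, a nectin cell adhesion gene, had log2 fold changes of -1.03 and 0.79.

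Of 11807 genes tested in both cell lines, 77 were called in the same direction in both, where independent lists give 33.8, and 57 in opposite directions, where independent lists give 33.8. The 52 genes higher in both exceeded the 16.9 of independent lists (Fisher's exact test, 2-sided, p = 6.90e-16), and the 25 lower in both exceeded 16.9 at p = 0.0419 in the same exact test. There were 34 genes higher in SEM and lower in RS4;11 against 16.2 (exact p = 1.21e-05) and 23 the other way against 17.6 (exact p = 0.185). An exchange of the labels of both SEM groups could not be excluded, and with it the numbers would be 57 in the same and 77 in opposite directions. The 11807 genes are not independent replicates, but the exact tests treat them as such, so their p can overstate the evidence for a shared response. The tests also take every gene as equally likely to be called, while genes with high counts can be called more readily in both fits. An excess over independent lists, present in opposite directions too, is thus no evidence of a shared response by itself. Of the 134 genes called in both, 57.5% moved the same way, with a Pearson correlation of 0.11. Across all 11807 genes the log2 fold changes had a Pearson correlation of 0.12 and a Spearman correlation of 0.11. Without RS4;11 control library 3 the counts were 45 in the same and 36 in opposite directions, without RS4;11 siRNA library 2 they were 39 and 33, and with DESeq2 they were 51 and 44.

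**Figure D4:**
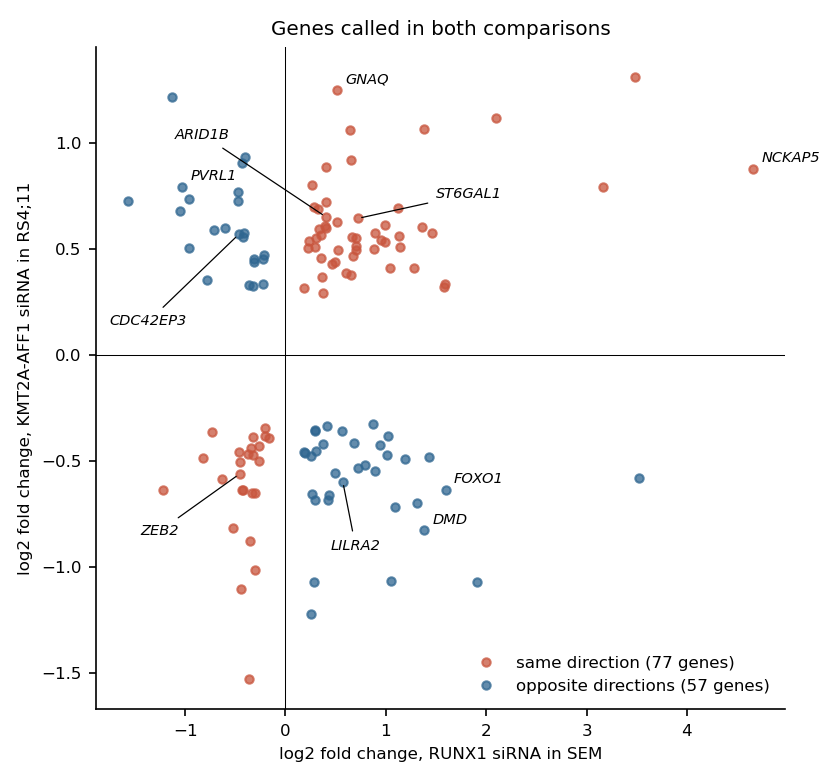
Each point is a gene called by edgeR in both cell lines, with its log2 fold change in SEM on the horizontal axis and in RS4;11 on the vertical axis (red, same direction; blue, opposite directions); the 5 of each kind with the smallest p under the naming rule are named. There are 77 genes in the same direction and 57 in opposite directions.

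The change of RUNX1 and KMT2A, named in advance, differed between the comparisons. The change in RS4;11 minus that in SEM was -0.45 for RUNX1 and -0.42 for KMT2A on the log2 scale, with edgeR adjusted p of 7.46e-05 and 0.000344 for the interaction. Of the 5 named genes called in the same direction, NCKAP5 (-3.78, adjusted p = 6.65e-16), GNAQ and ARID1B (0.25, adjusted p = 0.0394) differed in size, and ZEB2 (-0.10, 0.438) and ST6GAL1 (-0.07, 0.677) were not shown to differ (edgeR). For FOXO1 it was -2.23 with an edgeR adjusted p of 1.26e-10. Among B-cell genes it was -1.91 for RAG2, -2.93 for BLNK and -0.80 for CD22, with edgeR adjusted p of 1.13e-10, 1.34e-08 and 5.64e-07. EGR1 differed the other way, at 1.73, with an edgeR adjusted p of 5.15e-05. FOXO1 was chosen for opposite calls, and RAG2, BLNK, CD22 and EGR1 as list members with the smallest p in SEM, so the choice fixed or favoured a difference and these p are no separate evidence of one. Of 13746 genes tested for a difference, 785 had a change in RS4;11 above that in SEM and 950 below it. Without SEM siRNA library 1 the numbers were 467 and 742, without SEM siRNA library 2 618 and 836, and without SEM siRNA library 3 532 and 840. The siRNA target and the cell line differ together here, so a difference may come from either or both. With the labels of the SEM groups exchanged, every SEM direction would turn, and the differences under that exchange were not tested.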

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

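The tests of silent genes in the other RUNX1 siRNA libraries, of the spread of the SEM controls on the stress list and of swapped or exchanged SEM labels, and the sorting of the splits for the difference by their SEM groups, were chosen only after the result was seen.

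The change in RS4;11 minus the change in SEM, tested as an interaction in edgeR, was past the threshold for 4 of the genes named in advance and for the 5 named genes called in opposite directions. It was -0.45 for RUNX1 (adjusted p = 7.46e-05), -0.42 for KMT2A (0.000344), -0.35 for AFF1 (0.00520) and -0.37 for MYC (0.0362). It was 1.83 for PVRL1 (1.17e-11), -2.23 for FOXO1 (1.26e-10), -2.20 for DMD (1.47e-07), -1.16 for LILRA2 (8.41e-08) and 1.04 for CDC42EP3 (5.36e-08). These 5 were chosen as called in opposite directions with the smallest p, so a difference was fixed by the choice and their p is no separate evidence. The siRNA target and the cell line differ together, so these differences cannot be assigned to either. All differences together numbered 1735 genes, and 3 of 60 splits of the libraries within each cell line gave as many, the real one included, with up to 1970 in the others. The 8 other splits drawn with the real SEM groups gave 1173 to 1970 genes, and splits that broke these groups up gave 5 at most. Splits that keep the SEM groups keep the SEM change, so the number follows those groups and the splits do not say whether chance is excluded for it.

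SEM RUNX1 siRNA library 1 had a count in 2230 genes that had none in the other 11 libraries, where such genes numbered 32 to 93 per library, which is a signal outside the genes tested. Over the 6193 genes silent in all other libraries it held 3522 counts, or 0.0266% of the library, with at most 12 in a gene. RNA of another cell type or sample was predicted to put a large share of these counts in the 10 highest genes, and they held 2.16%. In whole libraries the 10 highest genes held 2.02% to 2.28% in SEM and 2.20% to 2.40% in RS4;11. RNA of another such library could thus give this share too, so the share cannot decide and that source stays open. The other siRNA libraries, 2 and 3, had 17122 and 17285 detected genes, against 20728 in library 1 and 16827 to 17141 in the controls. The lower of that pair had 0.999 times the genes of the highest control, but this ratio cannot decide on an opening of silent genes. The bound set for an opening lay above the 26364 genes counted. Genes with a count in libraries 2 or 3 were also left out of the silent set. The counts followed exonic length with a Spearman rho of 0.419 across genes, just past the bound of 0.4 set before, so genomic DNA in this library is a candidate source and stays open. No biological explanation beyond the siRNA was tested.

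Of 18 stress response genes 11 were lower in the SEM libraries labelled RUNX1 siRNA, with a list median of -0.41 on the log2 scale and a camera adjusted p of 3.05e-06 (adjusted p = 0.545 with an estimated correlation). The values argued against control library 3 as the whole cause, since without it 10 members were lower and the camera adjusted p was 4.54e-08, although the adjusted p was 0.577 with an estimated correlation. The range of the list's median over the 3 controls was 0.732 times the list's fall, so a culture state that varies between libraries whatever the siRNA may account for part of it. Its cause stays open, as does an effect of the RUNX1 siRNA.

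RUNX1 was not lower in the SEM libraries labelled RUNX1 siRNA. A swap of single libraries between the groups was argued against, since 0 of the 6 libraries correlated best with a library of the other group. An exchange of both groups' labels cannot be told apart from the labels as given, because RUNX1 did not pass (edgeR adjusted p = 0.0796), although it passed in 4 of 17 alternatives (0.0281 with library totals alone, 0.0466 with limma-voom, 0.0485 under upper quartile scaling and 0.0495 without control library 3), each time higher, the side an exchange predicts. With such an exchange every SEM direction would turn. An siRNA that acts on mature RNA and leaves synthesis unchanged may give the same values, and this was not tested, as protein and total RNA were not analysed here.

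Other splits of the same libraries were run for each count. The real SEM groups gave 4722 genes and the highest other split 0, and the real RS4;11 groups gave 206 and the highest other split 0. In both cell lines 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. Each other split mixed siRNA and control libraries, so part of the siRNA change stays in it and part adds to its spread. The numbers of the other splits, for genes and for lists, therefore do not show what chance alone gives. Camera passed 7 lists in SEM, where 6 of 10 splits gave as many and the highest other gave 9, and 7 lists in RS4;11, where 3 of 10 gave as many and the highest other gave 8, again with too few splits for a share under 0.05. For genes called in both comparisons, 1 of 100 splits gave as many as the 77 in the same direction and 1 of 100 as many as the 57 in opposite directions, with 0 in the highest other split of each. As every other split of either cell line called 0 genes, those 0 were fixed in advance, so this says nothing on the overlap beyond the 10 splits of each line.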

How the results depend on the processing

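The alternatives with thinned counts, with the B-cell list without CD24 and with SEM libraries left out as a pair were chosen only after the result was seen. Of 106 called named genes in SEM 93 kept their direction and call in every alternative that fitted the genes again, and of 41 in RS4;11 26 did. With a library left out, 8 and 15 lost the call. The stricter p and the fold of 1.5 were applied to counts of genes only. Some of the kept genes changed less than 1.5-fold, BCL2 in SEM and MYC in RS4;11 among them. Of the 7 lists called by camera in each cell line 1 kept its call when 1 planned choice was changed at a time, the B-cell list in SEM and the KMT2A fusion targets in RS4;11. With an estimated correlation and a further change those calls were lost in part. A block or fewer libraries also leave that test fewer degrees of freedom, so these losses do not measure gene correlation. The B-cell list then had an adjusted p of 0.0538 without CD24, 0.328 with the replicate block, 0.316 without the pair of SEM libraries and 0.0770 to 0.128 without 1 library. The KMT2A fusion targets had 0.0735 with upper quartile scaling, 0.0664 with library totals alone, 0.0987 with no filter, 0.264 with the block and 0.0799 to 0.215 without 1 library. Fry, which tests whether a list moves on balance and does not compare it with other genes, passed 12 SEM lists that camera did not, at adjusted p from 0.00687 (erythroid) to 0.0263 (KMT2A fusion targets), NF-kappaB (0.0123) and polycomb (0.0140) among them, and the RUNX family in RS4;11 (0.0123). Camera calls lost with fry were the histones in SEM (0.103) and 6 lists in RS4;11, from 0.0860 to 0.616. By construction, an adjusted p under 0.01 lowered the counts, to 1451 lower genes in SEM, 46 higher and 56 lower in RS4;11, 353 above and 587 below for the difference, and 38 in the same and 25 in opposite directions in both. A fold of at least 1.5 gave 1032 higher and 375 lower in SEM, 41 and 46 in RS4;11, 294 above and 622 below for the difference, and 12 in the same and 13 in opposite directions. With no filter there were 180 higher genes in RS4;11, and 119 in the same and 91 in opposite directions, and DESeq2 gave 51 in the same direction; the cause was not tested. With SEM counts thinned to the RS4;11 depth 1608 genes were higher and 1563 lower in SEM, fewer than at full depth but more than the 100 and 106 in RS4;11, so depth alone did not set the comparisons apart. In simulated counts at the SEM and RS4;11 depths, 36% and 26% of the smallest changes and 76% and 80% of 1.5-fold changes were called. Only 200 genes were changed in each simulation, against 4722 called in the real SEM data, and the cut-off on the unadjusted p loosens as more genes change. These shares therefore do not say how readily the 2 real comparisons find changes. Without RUNX1 siRNA library 1 and control library 3, 1627 were higher and 1312 lower.

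Leaving out a library at a time gave 1847 to 2561 higher and 1540 to 2679 lower genes in SEM, 50 to 143 higher and 53 to 109 lower in RS4;11, and 467 to 758 above and 742 to 975 below for the difference. In both comparisons 39 to 95 genes then had the same and 33 to 66 opposite directions. The replicate number as a block gave 171 higher and 154 lower genes in RS4;11, against 100 and 106 in the main fit. It gave 112 genes in the same and 90 in opposite directions, against 77 and 57. The p53 list in RS4;11 then had a camera adjusted p of 0.0427. Residuals of libraries with the same number correlated at -0.02, -0.12 and 0.00 in SEM, where those with different numbers ran from -0.12 to 0.13. In RS4;11 the same-number residuals correlated at 0.11, -0.07 and 0.13, against -0.16 to 0.04 for different numbers. The numbers showed no pairing in SEM, and a pairing in RS4;11 is not settled by these values. The sign of MYC in SEM turned without control library 1, to 0.015, against -0.16 at the lowest. That of CASP9 in RS4;11 turned without control library 2 (0.081) or siRNA library 3 (0.093), against -0.23 at the lowest. Lists also turned direction, in fits where they were not past the threshold, and the cause was not tested. With no filter these were the microRNA list in SEM (camera adjusted p = 0.944) and the erythroid list in RS4;11 (0.783), and without the pair of SEM libraries the microRNA list (0.870). Over the fits without 1 library, the lists that turned in some of them had camera adjusted p from 0.655 to 0.998 (microRNA, SEM) and, in RS4;11, from 0.612 to 0.917 (microRNA), 0.391 to 0.909 (myeloid), 0.506 to 0.962 (apoptosis), 0.716 to 0.939 (cytokine receptors), 0.576 to 0.962 (heat shock) and 0.000130 to 0.962 (histones, past the threshold without siRNA library 1).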

Other observations

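In SEM, signalling genes moved both ways. Of all genes tested there 34.4% were called, so a share of called members near that does not set a list apart. STAT5A, a transcription factor of cytokine signalling, rose from 12.4 ± 1.38 to 33.1 ± 1.16 CPM and the interleukin-7 receptor gene IL7R from 385 ± 12.7 to 497 ± 14.7 CPM (SD, n = 3), and of 14 cytokine receptor and JAK-STAT genes 5 were higher and 3 lower, 6 and 5 when adjusted over the list alone (camera adjusted p = 0.354). Of 19 immediate early genes 5 were higher and 7 lower, with the same numbers over the list alone (0.298), and EGR1 fell from 156 ± 7.18 to 75.4 ± 10.1 CPM (SD, n = 3) while NR4A2 rose by 0.76 on the log2 scale. Of 21 interferon response genes 4 were higher and 2 lower, 4 and 2 over the list alone (0.580), with MX2 at a log2 fold change of 1.34 and OAS2 at 0.97. Of 14 NF-kappaB targets 5 were higher and 2 lower, 5 and 2 over the list alone (0.298), with NFKB2 at 0.53. Of 23 apoptosis regulators 3 were higher and 6 lower, 3 and 6 over the list alone (0.298), and BMF, which promotes cell death, fell from 222 ± 14.7 to 124 ± 7.98 CPM (SD, n = 3). Of 18 p53 targets 7 were higher and 3 lower, 7 and 4 over the list alone (0.301), with the death receptor gene TNFRSF10B at 0.89 and the cell cycle inhibitor gene CDKN1A at -0.58. Of 16 polycomb genes 3 were higher and 6 lower, 3 and 6 over the list alone (0.298), with CBX7 at 0.62 and EED at -0.48. Of 13 heat shock genes 2 were higher and 5 lower (0.384), of 22 genes of the PAF1, super elongation and DOT1L complexes 1 was higher and 3 lower (0.298), and of 11 microRNA pathway genes 1 was higher, AGO2, and 1 lower, DGCR8 (0.927), each with the same numbers over the list alone. Of 20 ribosomal protein genes 3 were lower, and 0 over the list alone (0.298). Of 7 cyclin-dependent kinase inhibitor genes 1 was lower (0.393), of 3 T-cell genes 1 was higher, ZAP70 (0.298), and of 2 erythroid genes 1 was lower, TFRC (0.298), each with the same numbers over the list alone. Named members whose call was lost without a library, by edgeR adjusted p, were CASP9 of the apoptosis list (up to 0.153), RPL5 without control library 2 (0.0875) or siRNA library 1 (0.229), 2 (0.0664) or 3 (0.0551), RPL7 without control library 2 (0.0553) or siRNA library 1 (0.20) or 2 (0.0571), RPS3 without siRNA library 1 (0.0801) or 3 (0.0594), HSPB1 without control library 2 (0.0663), ELL2 without control library 2 (0.126) or siRNA library 1 (0.0817) or 2 (0.0866), IRF9 without control library 3 (0.0866) or siRNA library 2 (0.0828), and OAS3 without siRNA library 3 (0.113). Calls were also lost with DESeq2 for OAS3 (DESeq2 adjusted p = 0.0643), IRF9 (0.0621) and ELL2 (0.0536), with library totals alone for RPL5 (edgeR adjusted p = 0.0676), and with both cell lines in 1 fit for RPL7 (0.0547) and IRF9 (0.0683). With thinned counts 7 named members of these lists besides CASP9 lost theirs, at edgeR adjusted p of 0.0552 to 0.528. Of 4 stem and progenitor surface genes edgeR called 0, and 0 over the list alone (0.650). All other p in parentheses are camera adjusted p.

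In RS4;11, SOCS2, a feedback inhibitor of cytokine signalling, fell from 128 ± 12.6 to 73.1 ± 11.3 CPM (SD, n = 3), and of 14 cytokine receptor and JAK-STAT genes 2 were higher and 1 lower, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.927). The higher members were SOCS1, whose call was lost without control library 2 (edgeR adjusted p = 0.0583), and FLT3, also of the stem and progenitor list, whose call was lost without any 1 of 5 libraries (up to 0.273). Of 4 RUNX family genes 1 was lower, RUNX1 (0.0605), and of 21 genes of the PAF1, super elongation and DOT1L complexes 2 were lower, AFF1 and KMT2A (0.189), the same over the list alone. The calls of KMT2A and RUNX1 were lost without some libraries, at edgeR adjusted p of up to 0.144 and 0.0706. Of 4 stem and progenitor surface genes 1 was higher and 1 lower, 1 and 1 over the list alone (0.134). Of 17 p53 targets 1 was higher, TNFRSF10B, 3 higher and 1 lower over the list alone (0.0611, and past the threshold in 3 of 14 alternatives, 0.0491 without control library 1 and 0.0349 without siRNA library 1 among them), and the call of TNFRSF10B was lost without control library 2 (edgeR adjusted p = 0.0819) or 3 (0.0822) or siRNA library 2 (0.100). Of 19 interferon response genes 1 was lower, USP18, 1 also over the list alone (0.0605, and 0.0161 without control library 2 and 0.0287 without siRNA library 2). The call of USP18 held in 8 of 14 alternatives and was lost with limma-voom (limma adjusted p = 0.0558) and without control library 1 (0.0972), 2 (0.0515) or 3 (0.231) or siRNA library 1 (0.208) or 2 (0.114), edgeR adjusted p. Lists with 0 members called by edgeR were apoptosis regulators (0.844), NF-kappaB targets (0.218; 2 higher over the list alone), heat shock (0.844), polycomb (0.776; 1 lower over the list alone), myeloid (0.905; 1 higher and 1 lower), erythroid (0.905; 1 lower), T-cell (0.218; 1 higher), microRNA (0.939), G1 and S phase (0.218), cyclin-dependent kinase inhibitors (0.131, and 0.0131 without control library 2; 1 lower over the list alone), the stress response (0.218, and 0.0170 without control library 2) and histones (0.218, and 0.000130 without siRNA library 1). Camera's direction was down for the erythroid list and up for the microRNA list, whose medians were 0.16 and -0.01 and means 0.05 and 0.00, and the myeloid list had a median of -0.13 and a mean of 0.02. At an unadjusted p under 0.05 edgeR had 1383 genes in this comparison, DESeq2 called 71 higher and 72 lower and limma-voom 102 and 106. All other p in parentheses are camera adjusted p.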
